A study of Mus musculus with 17 samples.

How the data were processed

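Liver RNA of male mice with loxP-flanked (floxed) Gata4 alleles was profiled in 17 libraries of 4 groups. RNA was purified with TRIzol and spin columns, and libraries were prepared with the KAPA mRNA Hyperprep kit, per the labels' protocols. An adeno-associated virus of serotype 8 (AAV8) carried Cre recombinase under the hepatocyte promoter Tbg in the arm labelled Gata4LKO and no transgene in the control arm. The Cre cargo and the Gata4 genotype therefore cannot be separated in this design.

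The authors deposited one table of normalized counts and 5 tables of comparisons. Alignment used STAR 2.6.0c with the mm10 genome build, and FastQC and DESeq2 were also named, per the submitters' processing notes. The read counter, the gene annotation and the strand setting are not given in the sources used here. The values in the deposited table are a normalized signal, the reads per gene divided by 1 size factor per library, as the values themselves show. In each library, every value above 0 was a whole multiple of what 1 read was worth: 100% of values lay within 0.05 read of a whole number, the largest distance being 0.000532 read. The authors' comparison tables give a log2 fold change, a p-value and an adjusted p-value per gene, per the file headers.

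Gene symbols came from the deposited tables, where 422 of 24676 genes had no symbol and 29 genes were at 0 in every sample. Positions were taken from the GENCODE M21 annotation of the mm10 (GRCm38) mouse genome, which held 24656 of the 24676 gene identifiers. Every library column was matched to a sample through its name, and no column was left unmatched.

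Groups followed the sample titles. The treatment characteristic contradicted the title in 8 libraries, which make up 2 of the groups: the Gata4LKO vehicle group carried the GW3965 label and the control GW3965 group the vehicle label. The result tables listed in each sample's description went with the title, and so did the LXR target genes in the values, although values were not used to assign any sample. The age at treatment also differed between the series design text and the sample labels, which give 11 weeks. The labels do not state that each library came from a separate mouse. P-values then measure the spread between these libraries.

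Recovered reads in genes ranged from 11.8 to 22.05 M per library. Between replicates of a group, counts differed by far more than sampling noise in every pair, so no library was counted as a duplicate of another.

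The main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(normalized count + 1), with 1 coefficient per group, all 17 libraries in 1 fit, and Benjamini-Hochberg adjustment. Genes with a normalized count of at least 10 in at least 4 libraries were kept, which left 13379. A fold change is thus on the log2(value + 1) scale and understates the change of genes with low values. A gene was called at an adjusted p below 0.05. The comparisons were Gata4LKO against control with vehicle and with GW3965, GW3965 against vehicle in control and in Gata4LKO, and the interaction of genotype and treatment. On simulated data with 100 genes changed 2-fold and 100 changed 4-fold among the 13379, limma recovered 57% and 69% of them for genotype with vehicle, with 4 false calls. For genotype with GW3965 it recovered 56% and 83% (5 false calls). For GW3965 in control it recovered 57% and 90%, and for GW3965 in Gata4LKO 58% and 84%, with 6 false calls each. The simulated genes varied independently, with no structure between libraries. The changed genes planted also outnumbered those called between genotypes, which eases the adjusted threshold. Recovery in the data could therefore be lower.

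Before the data were examined, 27 gene lists were fixed. They covered LXR targets, lipogenesis, cholesterol synthesis and uptake, bile acids, lipoproteins, fatty acid oxidation and PPARA targets, glucose metabolism, pericentral and periportal hepatocyte genes, hepatocyte transcription factors, iron and haem, genes with male-biased or female-biased expression in mouse liver, drug metabolism, acute phase, interferon response, p53 response, cell cycle, unfolded protein and integrated stress response, the circadian clock, and mitochondrially encoded transcripts. Markers of liver sinusoidal endothelium, stellate cells and fibroblasts, Kupffer cells and macrophages, lymphocytes and recruited myeloid cells, cholangiocytes, and blood, adipose and pancreas completed the set. Some genes stand in more than one list. Lists were tested with camera in limma, which compares the members with all other genes, with a correlation between genes estimated from the data and adjustment over the 27 lists. For each list, members past the threshold are also counted with p adjusted over the list alone. The LXR target score was the mean of log2(normalized count + 1) over the list in each library and was tested with two-sided exact permutation tests. For the interaction this test exchanged treatment within genotype, and a second permutation test, added after the data were seen, did so after removing the treatment effect common to both genotypes. In 1000 simulations of a score with a treatment effect of 1, a difference of 0.8 between the responses and the group SDs of the LXR score, the first passed in 0% and the second in 93.6%; with no difference they passed in 0% and 5.8%.

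The groups, tests, alternatives and gene lists, and the rule for named genes, were also fixed before the data were examined. The rule named Gata4 in the genotype comparisons. It named up to 6 genes per direction with the largest change among those with an adjusted p below 0.05, a mean normalized count of at least 50 and no overlap between the groups compared, the last not required for the interaction. Genes with predicted or missing symbols were left out. It also named up to 4 members per list with the smallest p, and members of LXR targets, lipogenesis, bile acids and lipoproteins that went against their list. Some genes that the rule names are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

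Alternatives set beforehand were pseudocounts of 0.5 and 5, no filter, a filter of 50 in 4 libraries, upper-quartile scaling, equal totals, and edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads. The authors' deposited adjusted p-value, an added threshold of 1 on the absolute log2 fold change, sample weights, a fit of only the 2 groups compared, a preset correlation of 0.01, fry and leaving out each library in turn were set as well. Alternatives without 5 libraries with a high mitochondrial share, without 2 libraries with few genes detected, without both kinds, and with the mitochondrial share as a covariate were chosen after seeing the data. So was the genotype comparison over both treatments together. Other splits of the libraries were refitted in all cases up to 35, or in 100 draws where there were more.

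Reads of near-identical genes could have been divided between them in counting. This applies to Acot1 and Acot2, Saa1 and its paralogs, Scd1 and Scd2 to a smaller extent, the Cyp2c, Cyp2d, Cyp3a, Ugt2b, Hsd3b and Ces families, Selenbp2 and H2-Aa. Gm5345 is annotated as a processed pseudogene, so its reads could come from a related gene. Abcg5 (chromosome 17, 84658234 to 84683011, minus strand) and Abcg8 (84676302 to 84700333, plus strand) overlap in the annotation, and without a stated strand setting reads in the overlap cannot be told apart. Python 3.11.15 and matplotlib 3.10.9 drew the plots.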

Results

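Messenger RNA was measured in livers of male mice of mixed strain, 11 weeks old, in a cross of genotype and treatment. Mice with floxed Gata4, which encodes a zinc-finger transcription factor, had received a hepatocyte-directed Cre virus (Gata4LKO) or an empty virus (control) 1 week earlier. They were gavaged with GW3965, a synthetic agonist of the liver X receptors (LXR), at 40 mg/kg, or with vehicle (dimethylsulfoxide in canola oil), 17 h and 8 h before sacrifice, and had been fasted for 4 h. The groups were control vehicle (n = 4), Gata4LKO vehicle (n = 4), control GW3965 (n = 4) and Gata4LKO GW3965 (n = 5). Groups follow the sample titles, which the treatment labels contradict in the Gata4LKO vehicle and control GW3965 groups. Values are the authors' normalized counts, given as mean ± SD over libraries, with differences on the log2(normalized count + 1) scale, ± SE from the limma fit.

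Libraries held 11.8 to 22.05 M reads in genes. In 5 libraries, 15.6% to 32.6% of the normalized counts came from mitochondrially encoded genes, against 6.06% to 7.26% in the other 12. These were replicate 1 of control vehicle, replicates 10 and 13 of control GW3965, and replicates 17 and 18 of Gata4LKO GW3965. The 10 most abundant genes took 28.9% to 40.3% of the normalized counts in these 5 libraries and 18.6% to 24.03% in the other 12. Replicate 6 of Gata4LKO vehicle had 15515 genes above 0 and replicate 16 of Gata4LKO GW3965 15601, against 16456 to 19729 in the other 15. The first principal component held 22.5% of the variance and the second 13.4%.

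**Figure D1:**
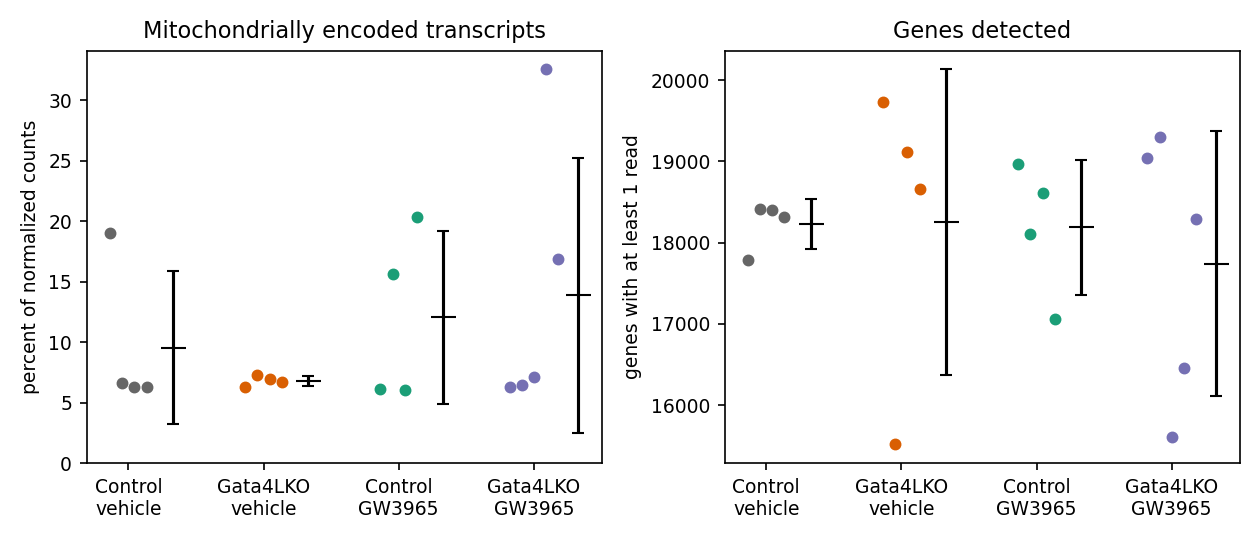
Share of normalized counts from mitochondrially encoded transcripts (%, left) and number of genes with at least 1 read (right, axis not from 0) in each of the 17 libraries, one point each, with the mean and SD of each group. The 5 libraries with a share of 15.6% to 32.6% fall in 3 of the 4 groups, and the libraries with 15515 and 15601 genes are both labelled Gata4LKO.

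The first comparison asks whether the targeted gene was lower in the libraries labelled Gata4LKO. Gata4 (ENSMUSG00000021944; chromosome 14, 63198922 to 63271692, minus strand, mm10) had a normalized count of 153 ± 27.3 in control vehicle and 194 ± 44.2 in Gata4LKO vehicle libraries. With GW3965 it was 221 ± 44.1 in control and 219 ± 41.2 in libraries labelled Gata4LKO. The fold of Gata4LKO over control was 1.25 with vehicle (95% interval 0.928 to 1.69; limma adjusted p = 0.910) and 0.992 with GW3965 (0.746 to 1.32; limma adjusted p = 0.999). Single control vehicle libraries had 128, 169, 183 and 132 normalized counts of Gata4, and Gata4LKO vehicle libraries had 181, 137, 234 and 223. With GW3965, control libraries had 164, 254, 258 and 209, and libraries labelled Gata4LKO had 260, 194, 244, 160 and 239. The Gata4 counts thus did not show the difference the labels name. Every genotype comparison here is between libraries labelled Gata4LKO and libraries labelled control. Which exons were floxed is not given in the sources used here, and a whole-gene count includes reads from exons outside the deleted part, so it checks the labels only in part.

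**Figure D2:**
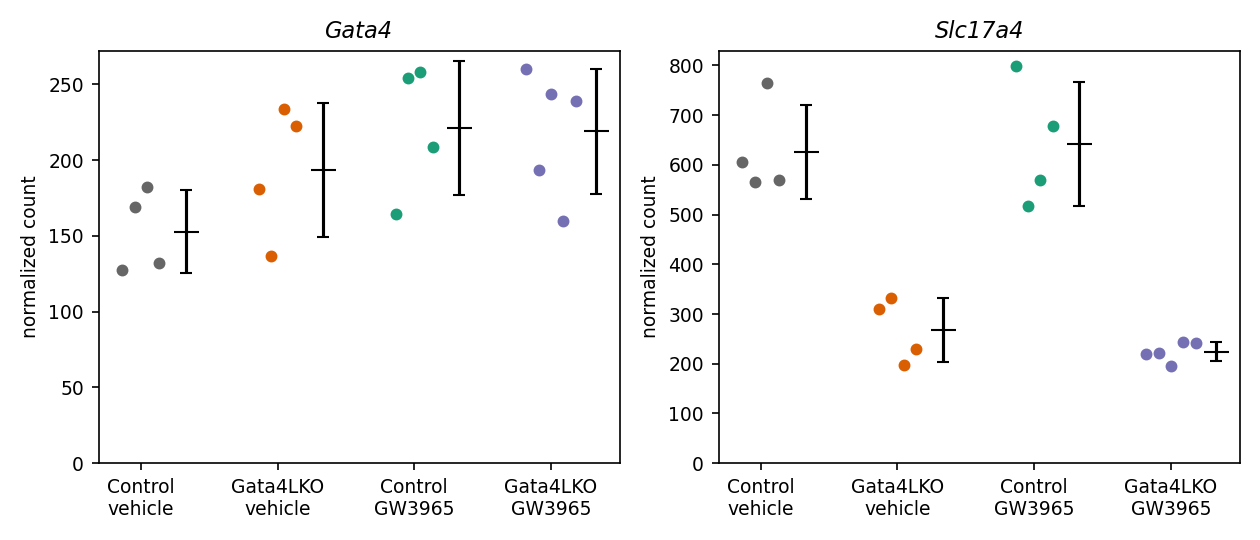
Normalized counts of Gata4 and Slc17a4 in each library of the 4 groups, with the group mean and SD. Gata4 overlaps between genotypes, while Slc17a4 lies at 196 to 331 in the 9 libraries labelled Gata4LKO and at 517 to 799 in the 8 controls.

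With vehicle, the libraries labelled Gata4LKO had less Slc17a4 and Sult1e1 mRNA than controls. All 4 Gata4LKO vehicle libraries also had values near 0 of the pseudogene Gm5345, described below, and none of the 4 controls did. Genotype and that split of the libraries cannot be told apart in this comparison. Slc17a4 encodes an organic anion transporter (chromosome 13, 23895890 to 23915009, minus strand). It was at 626 ± 94.5 in control and 267 ± 64.1 in Gata4LKO libraries (n = 4 each), a log2 difference of -1.25 ± 0.17 (limma adjusted p = 0.0133). Sult1e1 (chromosome 5, 87575969 to 87591594, minus strand), the oestrogen sulfotransferase, was at 101 ± 37.5 and 12.8 ± 4.34, a log2 difference of -2.88 ± 0.44 (limma adjusted p = 0.025). All 14 markers of Kupffer cells and macrophages had positive log2 differences in the Gata4LKO group, with a median of 0.56 (camera adjusted p = 0.0413). This list call was lost in most fits that left out 1 library. Of these 14, 10 were higher when adjusted over the list alone and 0 when adjusted over all genes. Examples are the secreted macrophage protein Cd5l, at 611 ± 124 and 1129 ± 135 (log2 0.90 ± 0.21), the receptor Csf1r (0.76 ± 0.19), the complement component C1qc (0.93 ± 0.24) and Vsig4 (0.54 ± 0.16).

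Most genes of cholesterol and fatty acid synthesis had lower values in the Gata4LKO vehicle group, but camera called neither list. All 24 tested genes of cholesterol synthesis and uptake had negative log2 differences, with a median of -0.33 (camera adjusted p = 0.335). Of these, 3 were lower when adjusted over the list alone, among them Pmvk (-0.62 ± 0.18) and Ebp (-0.31 ± 0.09). In lipogenesis, 13 of 16 differences were negative (median -0.48, camera adjusted p = 0.368). The desaturase Fads1 was lower when adjusted over the list alone (-0.48 ± 0.11). Among the lipoprotein genes (median -0.16, camera adjusted p = 0.335), Mttp, needed for assembly of apolipoprotein B particles, was lower when adjusted over the list alone (-0.47 ± 0.10) and the sorting receptor Sort1 higher (0.71 ± 0.20). Apoa1 differed by -0.57 ± 0.18 and did not pass. Of 26 genes of fatty acid oxidation and PPARA targets, 22 had positive values (median 0.17, camera adjusted p = 0.610), and the pantetheinase Vnn1 passed when adjusted over the list alone (1.36 ± 0.32). Also past the threshold when adjusted over the list alone were the glycolytic regulator Pfkfb1 (-0.54 ± 0.15), pericentral Lect2 (-0.67 ± 0.15) and Rnf43 (0.89 ± 0.21), the clock gene Arntl (-1.75 ± 0.49) and male-biased Selenbp2 (-0.96 ± 0.26). So did the leukocyte genes Ptprc (0.71 ± 0.24), Cd74 (0.92 ± 0.31) and H2-Aa (1.10 ± 0.39), in a list whose median was -0.08 and whose mean was 0.15 (camera adjusted p = 0.709). None of these list members passed over all genes. Of the libraries with a high mitochondrial share, 1 was among the 4 control vehicle libraries and 0 among the 4 of Gata4LKO vehicle.

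Over all 13379 genes, limma called 2 for genotype with vehicle, 0 higher and 2 lower, and 823 had an unadjusted p below 0.05 where chance gives 669. By edgeR 2 genes passed, by DESeq2 on the recovered reads 49, and 51 passed in the authors' deposited table (19 higher and 32 lower), both genes called here among them. Slc17a4 lost its call without replicate 1 or 3 of control vehicle or replicate 7 of Gata4LKO vehicle, each of which left 0 genes, with the highest adjusted p = 0.102 without replicate 3. Sult1e1 and the Kupffer list each lost their call in 6 of 8 such fits, the list with a camera adjusted p up to 0.0883 (without replicate 5). Without the 5 libraries with a high mitochondrial share, of which this comparison holds replicate 1 of control vehicle, 14 genes were called, both of the 2 among them. The Kupffer list then had a median of 0.68 with all 14 positive and a camera adjusted p = 0.176; without replicate 1 alone it kept its call (camera adjusted p = 0.0293).

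With GW3965 in both genotypes, the libraries labelled Gata4LKO again had less Slc17a4, at 225 ± 19.3 (n = 5) against 641 ± 125 in control (n = 4), a log2 difference of -1.49 ± 0.16 (limma adjusted p = 4.70e-04). The carboxylesterase Ces2a was at 2274 ± 392 against 4279 ± 542 (-0.92 ± 0.12, limma adjusted p = 0.00246), and the fatty acid-binding protein Fabp2 at 274 ± 28.5 against 1102 ± 565 (-1.89 ± 0.29, limma adjusted p = 0.0205). The succinate receptor Sucnr1 (-1.12 ± 0.20), the membrane protein Gpr155 (-0.85 ± 0.15) and the steroid dehydrogenase Hsd17b2 (-0.77 ± 0.13) were lower as well. Lcn2, which encodes the siderophore-binding lipocalin 2, was at 202 ± 37.7 against 56.2 ± 28.3 (1.91 ± 0.31, limma adjusted p = 0.0301). The secreted glycoprotein gene Adamtsl2 was at 131 ± 33.8 against 52.1 ± 19.6 (1.33 ± 0.23, limma adjusted p = 0.037).

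All 24 genes of cholesterol synthesis and uptake had negative values in this comparison too, and 13 were lower when adjusted over the list alone, against 0 over all genes. Among them were Sc5d (-0.65 ± 0.15), Mvd (-1.50 ± 0.35) and Insig1 (-0.70 ± 0.17). The list median was -0.48 (camera adjusted p = 0.106). Of 16 lipogenic genes, 15 had negative values and 9 were lower when adjusted over the list alone (median -0.60, camera adjusted p = 0.129). Elovl6 was at -0.91 ± 0.23, Acly at -0.89 ± 0.23, Elovl5 at -0.52 ± 0.16 and Acacb at -0.96 ± 0.31. Markers of stellate cells and fibroblasts had the opposite sign, with 11 of 14 positive (median 0.43, camera adjusted p = 0.106). When adjusted over the list alone 5 were higher, such as Dcn (0.60 ± 0.14), Reln (0.52 ± 0.15) and Hand2 (0.61 ± 0.21). Of 15 genes with male-biased expression, 14 had negative values (median -0.81, camera adjusted p = 0.141). Hsd3b5 (-2.09 ± 0.48), Selenbp2 (-1.04 ± 0.25) and Nudt7 (-0.95 ± 0.30) were lower when adjusted over the list alone. Without the libraries with a high mitochondrial share the median was -0.20 for male-biased genes, with 5 of 15 positive, and 0.14 for stellate markers, with 10 of 14 positive (camera adjusted p = 0.764 for both).

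Single members of further lists passed when adjusted over the list alone. They were the bile acid conjugating enzyme Baat (-0.62 ± 0.12) and Cyp2c70 (-0.85 ± 0.23) in bile acids, Mttp in lipoproteins (-0.38 ± 0.10), and Cyp3a11 in drug metabolism (-0.79 ± 0.24). The haem synthesis gene Alas1 was at 0.92 ± 0.25 in iron and haem, erythroid Alas2 at -0.84 ± 0.19 in the blood list and periportal Cyp2f2 at -0.69 ± 0.18.

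Over all genes, limma called 8 for genotype with GW3965, 2 higher and 6 lower (865 at an unadjusted p below 0.05, 669 expected by chance). Camera called 0 of 27 lists with an estimated correlation (7 at an unadjusted p below 0.05), and fry called 0. Of the genes in the authors' deposited table, 77 passed (20 higher and 57 lower), among them all 8. Leaving out single libraries, only Slc17a4 and Ces2a of the 8 kept their calls in all 9 fits; the count was 2 without replicate 14 or 18 and 21 without replicate 17 of Gata4LKO GW3965, 3 without replicate 12 or 13 and 4 without replicate 9 of control GW3965. Without the 5 libraries with a high mitochondrial share, 2 of control and 2 of Gata4LKO among those compared here, 9 genes were called, 2 of them among the 8.

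Slc17a4 was the gene lower in both genotype comparisons, where independent lists of 2 and 6 genes would share 0.000897. Leaving out single libraries gave 0 to 2 shared genes, and leaving out the 5 with a high mitochondrial share gave 3. Over all genes the genotype differences with vehicle and with GW3965 had a Pearson correlation of 0.0479 (Spearman 0.0587), across genes, which are not independent replicates.

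The response to GW3965 was measured first in control livers. Scd2, a stearoyl-CoA desaturase (chromosome 19, 44293674 to 44306864, plus strand), was at 76.6 ± 16.5 with vehicle and 451 ± 122 with GW3965 (n = 4 each), a log2 difference of 2.53 ± 0.20 (limma adjusted p = 4.65e-06). Its neighbour Scd1 (44394455 to 44407879, minus strand), the main hepatic form, changed by 3.10 ± 0.60 (limma adjusted p = 0.0215). The peroxisomal enzymes Ehhadh (2.61 ± 0.38) and Acaa1b (2.49 ± 0.31), the thioesterase Acot1 (2.61 ± 0.45) and the ADAM family gene Adam11 (3.17 ± 0.48) rose too. Sult1e1 fell from 101 ± 37.5 to 15.7 ± 9.70 (-2.70 ± 0.44, limma adjusted p = 0.00793) and Lcn2 from 234 ± 127 to 56.2 ± 28.3 (-2.01 ± 0.33, limma adjusted p = 0.00793).

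The other genes named for their falls were the methyltransferase Nnmt (-2.53 ± 0.49), the phosphatidate phosphatase Lpin1 (-1.94 ± 0.39), the ferritin receptor Scara5 (-1.59 ± 0.36) and the olfactory receptor gene Olfr1034 (-1.32 ± 0.23). Of 18 LXR targets, 17 had positive values, 11 rose over all genes and 12 when adjusted over the list alone (median 0.99, camera adjusted p = 0.00664). Among them were the sterol transporters Abcg8 (1.33 ± 0.18), Abcg1 (1.88 ± 0.29) and Abca1 (1.17 ± 0.18) and the ubiquitin ligase Rnf145 (1.30 ± 0.22); Nr1h3, which encodes LXR alpha, was the negative member (-0.12 ± 0.12). Srebf1, the lipogenic transcription factor, chosen after its values were seen, was at 1311 ± 466 and 6442 ± 2701 (2.26 ± 0.40, limma adjusted p = 0.0136, and 0.0707 without replicate 10 of control GW3965). All 16 lipogenic genes had positive values, 8 rose over all genes and 13 when adjusted over the list alone, such as Elovl6 (1.88 ± 0.24) and Gpam (0.80 ± 0.16), with a median of 1.09 (camera adjusted p = 0.0156). Of 26 genes of fatty acid oxidation and PPARA targets, 22 were positive, 5 rose over all genes, Acot2 among them (1.92 ± 0.31), and 12 when adjusted over the list alone (median 0.46, camera adjusted p = 0.0802).

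Markers of Kupffer cells and macrophages had positive values in 13 of 14 cases in control livers given GW3965 (median 0.47, camera adjusted p = 0.0802). Cd5l rose over all genes (1.21 ± 0.21), and 6 markers were higher when adjusted over the list alone, with Cd68 at 0.86 ± 0.22, Timd4 at 1.37 ± 0.35 and Adgre1 at 0.95 ± 0.31. Acute phase genes had 1 positive value in 19 (median -0.33, camera adjusted p = 0.0802). Lcn2 fell over all genes, and 5 were lower when adjusted over the list alone, among them Steap4 (-0.56 ± 0.16), Mt1 (-1.27 ± 0.37) and Saa1 (-1.52 ± 0.45).

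In cholesterol synthesis and uptake, Cyp51 fell over all genes (-0.93 ± 0.21), and when adjusted over the list alone Sqle was lower (-1.02 ± 0.29) and Insig1 higher (0.76 ± 0.18; camera adjusted p = 0.647 for the list). Of the bile acid genes the transporter Abcc4 rose over all genes (1.66 ± 0.33), and Cyp2c70 (0.91 ± 0.25) and the flippase Atp8b1 (0.50 ± 0.15) passed when adjusted over the list alone (camera adjusted p = 0.672). Of the lipoprotein genes, Abca1 and the phospholipid transfer protein Pltp (0.95 ± 0.21) rose over all genes, and Apoa5 was lower when adjusted over the list alone (-0.63 ± 0.17; camera adjusted p = 0.647). Ces2a (0.73 ± 0.12) and the death receptor Fas (0.83 ± 0.18) rose over all genes. The gluconeogenic Pck1 (-1.14 ± 0.28), Lect2 (-0.59 ± 0.15), Cyp3a11 (0.94 ± 0.26) and female-biased Acot3 (2.44 ± 0.57) passed when adjusted over their lists alone.

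Limma called 106 genes for GW3965 in control, 81 higher and 25 lower (1199 at an unadjusted p below 0.05, 669 expected by chance), and all 106 also passed in the authors' deposited table, which held 221 (154 higher and 67 lower). Of the libraries with a high mitochondrial share, 1 of 4 vehicle and 2 of 4 GW3965 libraries entered this comparison. The count was 22, 66 and 45 without replicates 10, 9 and 12 of control GW3965, and 42, 31 and 37 without replicates 2, 3 and 4 of control vehicle; 12 of the 26 called genes tested in this way, Scd2, Ehhadh and Abca1 among them, kept their calls in all 8 fits. Without the 5 libraries with a high mitochondrial share 63 genes were called, 43 of them among the 106, and neither list passed (adjusted p = 0.120 for both, medians 0.93 and 0.98). Lipogenesis also lost its call without replicate 1 of control vehicle (adjusted p = 0.0631).

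**Figure D3:**
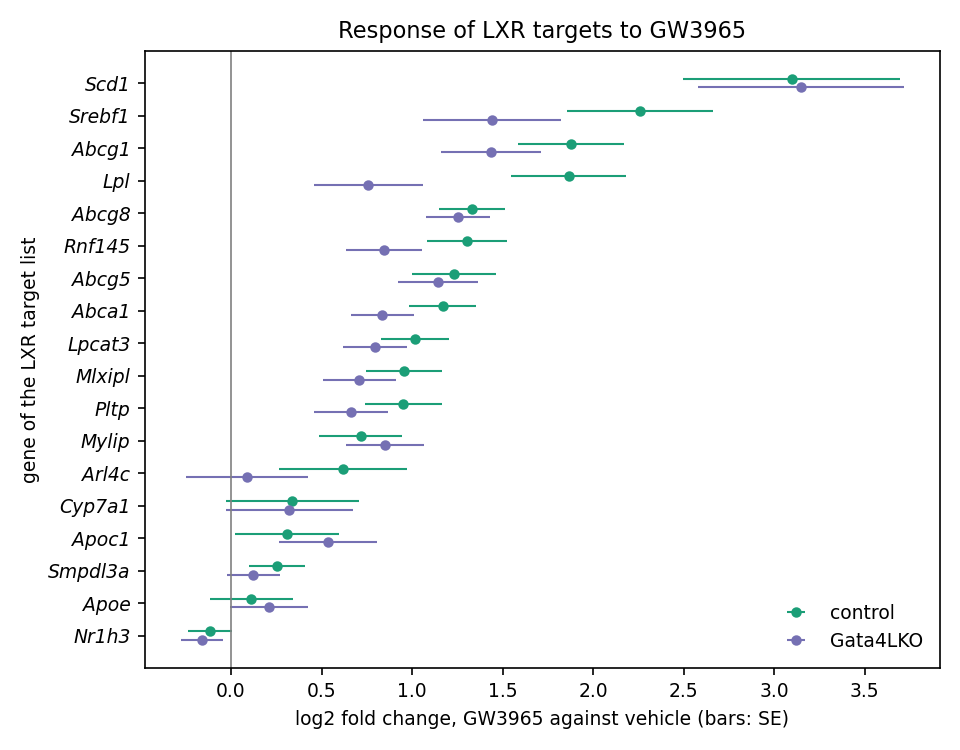
Log2 differences between GW3965 and vehicle for the 18 LXR targets in control and in libraries labelled Gata4LKO, with standard errors from the limma fit. In each genotype 17 of the 18 are positive, and Nr1h3 is the negative member.

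GW3965 was also compared with vehicle in libraries labelled Gata4LKO. Scd2 was at 84.1 ± 8.82 with vehicle (n = 4) and 447 ± 81.6 with GW3965 (n = 5), a log2 difference of 2.38 ± 0.19 (limma adjusted p = 5.16e-06). Scd1 (3.15 ± 0.57), Adam11 (2.28 ± 0.45), Ehhadh (2.20 ± 0.36), Acaa1b (1.83 ± 0.29) and the acyl-CoA synthetase Acsl3 (1.75 ± 0.25) rose as well. The squalene epoxidase Sqle fell from 707 ± 106 to 264 ± 43.8 (-1.42 ± 0.28, limma adjusted p = 0.0367). The cytochrome P450 gene Cyp2u1 (-1.31 ± 0.27), the adenosine receptor gene Adora1 (-1.27 ± 0.22), the replication factor Mcm10 (-0.79 ± 0.15) and the glucuronosyltransferase Ugt2b5 (-0.54 ± 0.11) fell as well.

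Of 18 LXR targets, 17 were positive in Gata4LKO livers, 4 rose over all genes and 12 when adjusted over the list alone (median 0.78; camera adjusted p = 0.0608 with an estimated correlation). Abcg8 (1.25 ± 0.17), Abcg5 (1.14 ± 0.22) and Abcg1 (1.44 ± 0.28) rose over all genes, and Abca1 (0.84 ± 0.17) and Srebf1 (1.44 ± 0.38) passed when adjusted over the list alone, while Nr1h3 had -0.16 ± 0.11. Of 16 lipogenic genes, 15 were positive, 4 rose over all genes, including Fads2 (1.28 ± 0.20) and Elovl6 (1.29 ± 0.23), and 11 when adjusted over the list alone (median 0.90; camera adjusted p = 0.071 with an estimated correlation). Of 26 genes of fatty acid oxidation and PPARA targets, 20 were positive (median 0.32, camera adjusted p = 0.419). Of these, 3 rose over all genes, Acot2 among them (1.57 ± 0.30), and 8 when adjusted over the list alone.

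Of the 24 genes of cholesterol synthesis and uptake, 5 were positive (median -0.26, camera adjusted p = 0.473). When adjusted over the list alone 5 were lower, with Cyp51 at -0.95 ± 0.20, Msmo1 at -0.96 ± 0.24 and Mvd at -1.38 ± 0.35, and 1 higher. Bile acid genes went both ways when adjusted over the list alone: Abcc4 (1.20 ± 0.31) and Cyp2c70 (0.77 ± 0.23) were higher, and Baat (-0.52 ± 0.12) and the sterol hydroxylase Cyp8b1 (-1.80 ± 0.49) lower (camera adjusted p = 0.956). Of the lipoprotein genes, Abca1 and Pltp (0.66 ± 0.20) were higher and Sort1 (-0.68 ± 0.19) lower when adjusted over the list alone (camera adjusted p = 0.761). All 15 male-biased genes were negative, with Hsd3b5 (-2.22 ± 0.48), Nudt7 (-1.24 ± 0.30) and Cyp2d9 (-0.91 ± 0.23) lower when adjusted over the list alone (median -0.76, camera adjusted p = 0.158). Without the libraries with a high mitochondrial share the median was -0.49, with 1 of 15 positive (camera adjusted p = 0.407).

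Markers of other liver cells had values of both signs with GW3965 in libraries labelled Gata4LKO. Kupffer and macrophage markers had a median of -0.08, and lymphocyte and myeloid markers a median of 0.0037 and a mean of -0.06 (camera adjusted p = 0.956 for each list). In sinusoidal endothelium 15 of 16 were positive (median 0.47, camera adjusted p = 0.258). When adjusted over the list alone 10 passed, among them Bmp2 (0.67 ± 0.19), Ehd3 (0.53 ± 0.17), Pecam1 (0.42 ± 0.14) and Mrc1 (0.56 ± 0.19). In stellate cells and fibroblasts 13 of 14 were positive, and Des (0.84 ± 0.21), Hand2 (0.87 ± 0.21), Dcn (0.57 ± 0.14) and Reln (0.46 ± 0.15) passed when adjusted over the list alone (median 0.40, camera adjusted p = 0.158). The transcription factor Gata6 (0.99 ± 0.23), Fas (0.61 ± 0.17), Xbp1 (-0.55 ± 0.14) and Alas2 (-0.90 ± 0.19) passed when adjusted over their lists alone. The 7 tested members of the list of mitochondrially encoded transcripts, which covers only part of these transcripts, had a median log2 difference of 0.89 in this comparison (camera adjusted p = 0.718). Of the libraries compared, 2 of the 5 with GW3965 and 0 of the 4 with vehicle had a high mitochondrial share. Without the libraries with a high share the list median was -0.04, with 3 of 7 positive.

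Limma called 33 genes for GW3965 in Gata4LKO, 27 higher and 6 lower (1599 at an unadjusted p below 0.05, 669 expected by chance). Among those higher were Gm16348 (6.69 ± 1.14) and Gm5345 (5.07 ± 0.81), chosen after their values were seen. Both were near 0 in every Gata4LKO vehicle library. A chromosomal segment that differs between mice, raised below, is a candidate explanation for these calls too. Camera called 0 of 27 lists with an estimated correlation (5 at an unadjusted p below 0.05), and fry called 4. All 33 genes also passed in the authors' deposited table, which held 188 (145 higher and 43 lower). The count was 11, 6, 13 and 16 without replicates 5, 6, 7 and 8 of Gata4LKO vehicle and 78, 17 and 10 without replicates 15, 16 and 18 of Gata4LKO GW3965. Leaving out any library, Scd2, Acaa1b, Acsl3, Abcg8 and Fads2 kept their calls in all 9 fits. Without the 2 libraries with few genes detected 4 genes were called, and without the 5 with a high mitochondrial share 23, of which 14 were among the 33.

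The GW3965 responses in the genotypes shared 16 of the 81 and 27 genes called higher, where independent lists would share 0.163. These were Scd1, Scd2, Elovl6, Fads2, Abcg1, Abcg5, Abcg8, Acaa1b, Acot2, Ehhadh, Adam11, Lipa, Inmt, Tmem135, Sema6d and Cert1, of which the last 5 were chosen after their values were seen. The predicted gene Gm26608, named for the same reason, was the 1 gene called lower in both (0.0112 expected). The 17 shared genes became 5 without replicate 5 of Gata4LKO vehicle, 27 without replicate 15 of Gata4LKO GW3965 and 9 without the 5 libraries with a high mitochondrial share. Of the 81 genes called higher in control, 75 were also positive in Gata4LKO, and 16 of the 25 called lower were negative. Over all genes the responses had a Pearson correlation of 0.251 (Spearman 0.312), across genes.

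The last comparison asks whether the response to GW3965 differed between genotypes. The LXR target score was 10.5 ± 0.0561 in control vehicle, 10.5 ± 0.119 in Gata4LKO vehicle, 11.5 ± 0.283 in control GW3965 and 11.4 ± 0.298 in Gata4LKO GW3965 libraries. GW3965 raised it by 1.07 in control (two-sided exact permutation p = 0.0286, the smallest that 70 permutations allow) and by 0.83 in Gata4LKO (exact permutation p = 0.0159, 126 permutations). The responses differed by -0.24 (exact permutation p = 0.664, 8820 permutations, treatment exchanged within genotype). The response to GW3965 itself widens the spread in that test, which therefore says little about a difference. With the treatment effect common to both genotypes removed first, a test added after the data were seen, the permutation p was 0.274. Leaving out single libraries gave -0.34 to -0.13, the latter without replicate 15 of Gata4LKO GW3965 or replicate 10 of control GW3965. Between genotypes the score differed by 0.06 with vehicle (exact permutation p = 0.514) and by -0.17 with GW3965 (exact permutation p = 0.421). Camera gave an adjusted p = 0.665 for the interaction in LXR targets and 0.759 in lipogenesis, and Scd1 (0.05 ± 0.83), Abcg8 (-0.08 ± 0.25) and Abca1 (-0.33 ± 0.25) did not pass.

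Sult1e1 and the processed pseudogene Gm5345 (chromosome 8, 40853828 to 40855027, minus strand; named after its values were seen) were the genes limma called for the interaction. Sult1e1 fell with GW3965 in control and was at 12.8 ± 4.34 with vehicle and 34.8 ± 20.1 with GW3965 in Gata4LKO, an interaction of 3.95 ± 0.60 on the log2 scale (limma adjusted p = 0.0374). Gm5345 was at 49.8 ± 14.8 and 20.4 ± 22.7 in control and at 0.796 ± 0.676 and 64.1 ± 34.8 in Gata4LKO, an interaction of 7.54 ± 1.18 (limma adjusted p = 0.0374). Its values fell into 2 sets, 0 to 1.64 in 6 libraries and 23.1 to 101 in the other 11, and control GW3965 held libraries of both. All 19 acute phase genes had positive interaction values (median 0.40, camera adjusted p = 0.204), and Lcn2 (2.26 ± 0.45) and Saa1 (2.14 ± 0.62) passed when adjusted over the list alone. Of 14 Kupffer and macrophage markers 13 were negative (median -0.69), and of 14 stellate markers 13 were positive (median 0.41), both with a camera adjusted p = 0.204; without the libraries with a high mitochondrial share the stellate median was 0.13, with 10 positive (camera adjusted p = 0.790). Of 21 interferon genes 18 were negative (median -0.45, camera adjusted p = 0.272). Sort1 (-1.14 ± 0.28), Ces2a (-0.96 ± 0.17), Gata6 (1.17 ± 0.33) and Alas1 (1.27 ± 0.37) also passed when adjusted over their lists alone.

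Limma called 2 genes for the interaction, both positive (622 at an unadjusted p below 0.05, 669 expected by chance), edgeR called 0, DESeq2 called 26 and 26 passed in the authors' deposited table (19 higher and 7 lower). Camera called 0 of 27 lists with an estimated correlation (4 at an unadjusted p below 0.05), and fry called 0. Sult1e1 lost its call in 13 of 17 fits that left out 1 library and Gm5345 in 14, and the count ranged from 0 to 9, the latter without replicate 13 of control GW3965. Without the 5 libraries with a high mitochondrial share neither passed: Sult1e1 was at 4.38 ± 0.62 (limma adjusted p = 0.0642) and Gm5345 at 8.26 ± 1.23 (limma adjusted p = 0.0674). Both were larger relative to their standard errors than with all libraries, so the smaller number of libraries ended the calls. The 1 gene called then was Syne3 (-1.98 ± 0.25, limma adjusted p = 0.0473), named after its values were seen.

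**Figure D4:**
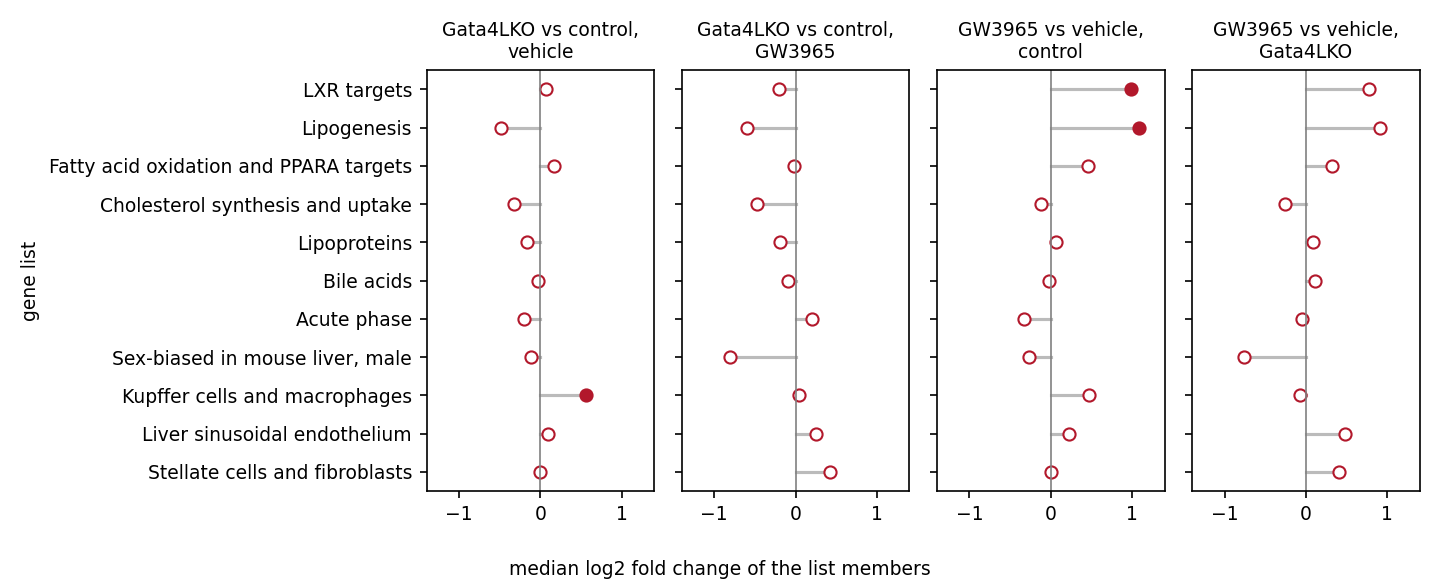
Median log2 difference over the tested members of 11 of the gene lists, one panel for each comparison other than the interaction; filled points are lists that camera called with an estimated correlation and open points those it did not. Medians run from 1.09 for lipogenesis with GW3965 in control to -0.81 for male-biased genes between genotypes with GW3965 (-0.20 without the libraries with a high mitochondrial share), and the filled points are LXR targets and lipogenesis with GW3965 in control and Kupffer cells and macrophages between genotypes with vehicle.

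In the remaining lists camera called none in any of the 5 comparisons with an estimated correlation. The lowest adjusted p over the comparisons was 0.184 for lipoproteins, 0.189 for bile acids and for drug metabolism, 0.208 for unfolded protein and integrated stress response, 0.209 for the p53 response, 0.250 for sinusoidal endothelium and 0.269 for the interferon response. It was 0.297 for glucose metabolism and for blood, adipose and pancreas, 0.473 for pericentral genes, 0.540 for female-biased genes and 0.610 for cholangiocytes. For periportal genes, hepatocyte transcription factors and lymphocytes and myeloid cells it was 0.647, for iron and haem 0.665, for the cell cycle 0.672, for mitochondrially encoded transcripts 0.718 and for the circadian clock 0.823. In lists called only with a preset correlation of 0.01, the estimated correlation ended the call; with it 1, 0, 2, 0 and 0 lists passed in the 5 comparisons as ordered above, against 8, 10, 9, 9 and 6. In 23 of the 135 pairs of list and comparison the median, the mean and the camera direction differed in sign, all with an adjusted p of at least 0.672.

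The genotype difference with vehicle and the GW3965 response in control use the same control vehicle libraries. Across genes they had a Pearson correlation of 0.437 and a covariance of 0.071. Over 100 simulated pairs of unchanged groups with shared controls the means were 0.484 and 0.0684. The simulated correlations ran from -0.246 to 0.855 and the covariances from -0.0148 to 0.195. These ranges hold both observed values and are too wide to show or exclude a shared effect. With the control vehicle libraries split so that none was shared, the correlation averaged 0.104 (-0.00768 to 0.201) and the covariance 0.0206 over 6 splits. In the authors' deposited table, log2 fold changes had a Pearson correlation across genes with those of limma of 0.946, 0.923, 0.957, 0.939 and 0.934 in the 5 comparisons as ordered above.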

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

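The tests on the mitochondrial share and on Gm5345 were chosen after those results were seen, and so was the genotype comparison over both treatments that the first test on Gata4 counts; the test of Gata4 against cell markers was chosen before.

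With Gata4 not lower in the libraries labelled Gata4LKO, if the genotype labels carried no difference, other splits within treatment would give as many genes; the real labels gave 30 over both treatments together, and 2 of 100 splits, the real one included, gave as many, which argues against this. The highest other split gave 1240 genes and separated the 5 libraries with a high mitochondrial share, with replicates 2 and 4 of control vehicle and replicate 5 of Gata4LKO vehicle, from the rest, so it follows a structure of the samples. Gata4 reads could come from endothelial and stellate cells, which Tbg-Cre would not reach. Over the 17 libraries, as deviations from group means, Gata4 had a Pearson r of 0.300 with the mean of 30 endothelial and stellate markers (permutation p = 0.306; Spearman rho 0.218, permutation p = 0.431; r = 0.274 without the 2 farthest libraries, 0.441 without those with a high mitochondrial share). This leaves it open, as are reads from exons outside the deleted part.

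In 5 libraries the mitochondrially encoded share was 15.6% to 32.6%, against 6.06% to 7.26% in the other 12; replicate 1 of control vehicle, at 19.0%, stood far from its group and also had the fewest detected genes in it (17780). Genotype or treatment as the sole cause is argued against by 3 of the 4 groups holding libraries of both kinds, but a contribution of treatment stays open (1 of 4 control vehicle, 0 of 4 Gata4LKO vehicle, 2 of 4 control GW3965 and 2 of 5 Gata4LKO GW3965 libraries). For lower sequencing depth, only 1 of the 5 lay below the lowest depth of the other 12, set by replicate 6 of Gata4LKO vehicle (14.9 M). Replicate 10 of control GW3965, at 20.1 M, argues against low depth for that library. Replicate 1 of control vehicle had 15.6 M, replicate 13 of control GW3965 15.4 M, and replicates 17 and 18 of Gata4LKO GW3965 11.8 and 15.7 M. A contribution of depth stays open for these, although replicate 2 of control vehicle had 15.5 M without a high share. A shift in GC content of the nuclear reads between library preparations was tested with the rank correlation of each library's deviation from its group mates with GC content: 3 of the 5 lay below each of the other 12, with a range of -0.50 to 0.0875 against -0.134 to 0.324. This argues against such a shift in all 5 and leaves it open for replicate 1 of control vehicle, replicate 13 of control GW3965 and replicate 17 of Gata4LKO GW3965; a second reference, using only group mates with a low share, was also run and gave the same 3 of 5. The labels give no batch, and tissue state or RNA quality, as well as a biological difference between animals, stay open as untested.

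Gm5345 had an interaction of genotype and treatment of 7.54 on the log2 scale in limma. It lay between 0 and 1.64 normalized counts in 6 libraries, the 4 of Gata4LKO vehicle and replicates 9 and 10 of control GW3965, and between 23.1 and 101 in the other 11. Genotype and treatment as the sole cause is argued against by 1 group, control GW3965, holding libraries on both sides of 10 normalized counts, and lower sequencing depth by only 1 of the 6 lying below the median depth of the other 11. A chromosomal segment that differs between mice of the mixed strain is a candidate explanation: of the 10 genes closest to Gm5345 in absolute correlation over the libraries, 2 lay within 5 Mb (Gm16348 and Asah1), and each of 100 random sets of 10 genes held fewer, at most 1. Aga (Pearson r = 0.844) and Enpp6 (0.825) lay farther away on chromosome 8. The rest were on other chromosomes, such as Tbcel (chromosome 9, -0.852) and Sult1d1 (chromosome 5, 0.851), both closer in absolute correlation than Asah1 (0.811). Whether the libraries differ more widely than in this segment was not tested. Gm16348 (chromosome 8, 41218139 to 41220894) was at 0 to 0.667 in the same 6 libraries and at 38.8 to 195 in the other 11; genotypes of the mice were not analysed here.

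The other gene limma called for the interaction was Sult1e1, at 3.95 on the log2 scale, a call lost in 13 of 17 fits that left out 1 library. Sult1d1, beside it on chromosome 5 (87554645 to 87569027), was among the 10 genes closest to Gm5345 (Pearson r = 0.851). Whether Sult1e1 follows the same split of the libraries as Gm5345 was not tested. Single libraries stood far from the others of their group in 14 of 120 groups of values tested over 30 measures. Normally distributed values would pass the cutoff about 1 time in 20. Counts need not be so distributed and the measures share the same libraries, so the 14 cannot be read as an excess. Adam11 was at 364 in replicate 6 of Gata4LKO vehicle and at 3087 in replicate 16 of Gata4LKO GW3965, and Acot1 at 749 and 1867 in the same libraries, the 2 with the fewest detected genes. Ehhadh was at 6093 and Acaa1b at 6978 in replicate 1 of control vehicle. In replicate 9 of control GW3965, Lcn2 was at 98.3 and Nnmt at 418. Adamtsl2 was at 81.3 in replicate 12 of control GW3965, Scd2 at 71.0 in replicate 8 and Sqle at 549 in replicate 5 of Gata4LKO vehicle, and Cyp2u1 at 249 in replicate 15 of Gata4LKO GW3965.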

How the results depend on the processing

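The alternatives without libraries picked by mitochondrial share or detected genes, with that share as a covariate, the LXR score interaction with the common treatment effect removed, and the genotype comparison over both treatments were chosen after the data were seen; the others were planned. Counts of genes are given in the order genotype with vehicle, genotype with GW3965, GW3965 in control, GW3965 in Gata4LKO and interaction, and were 2, 8, 106, 33 and 2 as reported; list counts were 1, 0, 2, 0 and 0. No count or score changed direction. With pseudocounts of 0.5 or 5 every count stayed within 1.5 times. DESeq2 on recovered reads gave 49, 81, 226, 200 and 26 genes, and 51, 77, 221, 188 and 26 passed in the authors' deposited table. Sample weights gave 193, 59, 247, 355 and 40. Equal totals gave 0, 1, 28, 14 and 0; with this scaling the median of all genes was 0.15 for genotype with vehicle and -0.14 for GW3965 in Gata4LKO, against -0.0081 and -0.0049 as reported. Fits of only the 2 groups compared gave 21, 1 and 19 in the first 3 comparisons. No filter gave 57 for GW3965 in control, a filter of 50 gave 0 for the interaction, edgeR gave 5 for genotype with GW3965 and 0 for the interaction, and a log2 threshold of 1 gave 5 for genotype with GW3965 and 62 for GW3965 in control. The cause was not tested for any of these, apart from the fewer samples or genes that an alternative itself uses.

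Lists called were 8, 10, 9, 9 and 6 with a preset correlation, 5 and 4 by fry for GW3965 in control and in Gata4LKO, and 0 for genotype with vehicle and 1 for GW3965 in Gata4LKO with upper-quartile scaling. Without the 5 libraries with a high mitochondrial share, 14 genes were called for genotype with vehicle, 63 for GW3965 in control and 1 for the interaction, 0 lists for genotype with vehicle and 0 for GW3965 in control, 3 genes were shared by the genotype comparisons and 9 by the GW3965 comparisons. Without the 2 libraries with few genes, 1 gene was called for genotype with vehicle, 4 for GW3965 in Gata4LKO and 0 for the interaction, and 0 lists for genotype with vehicle. Without all 7, 33 genes were called for genotype with GW3965, 184 for GW3965 in control and 8 for GW3965 in Gata4LKO. With the mitochondrial share as a covariate, 50, 202 and 4 genes were called for genotype with GW3965, GW3965 in control and the interaction, 0 lists for genotype with vehicle and 1 for GW3965 in Gata4LKO, and 128 genes for genotype over both treatments. Splitting the control vehicle libraries moved the correlation of the genotype and GW3965 differences to 0.104.

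Leaving out each library in turn gave 0 to 3, 2 to 21, 22 to 109, 6 to 78 and 0 to 9 genes, and 0 to 2, 0 to 1, 1 to 5, 0 to 1 and 0 to 0 lists. Over both treatments, genotype gave 9 to 57 genes and 0 to 4 lists. Shared genes were 0 to 2 for genotype and 5 to 27 for GW3965, and the interaction in the LXR target score was -0.34 to -0.13. Among genes named in a comparison, 247 values of called genes lost the call with the same direction, and 566 kept it. Gata4 with GW3965, at -0.01, turned positive with upper-quartile scaling (0.020), without replicates 10 (0.06) and 12 (0.07) of control GW3965, without replicates 15 (0.03) and 17 (0.10) of Gata4LKO GW3965 and without the libraries with a high mitochondrial share (0.16), all uncalled; leaving out single libraries gave -0.15 to 0.10. No paired analysis was possible because the replicate numbers run on across the groups and none is shared. Within control GW3965 the numbers skip from 10 to 12. Depth of 11.8 to 22.05 M reads in genes limits values near 10 normalized counts most.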

Other observations

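The genotype comparison over both treatments together, and all tests on it in the next paragraph, were chosen after the data were seen; the splits of the samples were chosen before.

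Taking the mean of the genotype differences with vehicle and with GW3965, limma called 30 genes, 6 higher and 24 lower in the 9 libraries labelled Gata4LKO than in the 8 controls (962 at an unadjusted p below 0.05). Slc17a4 was at a mean of 244 against 634 (log2 -1.37, adjusted p = 1.31e-05), followed by Fabp2 (-1.77, adjusted p = 9.66e-04) and Gpr155 (-0.82, adjusted p = 0.00224). Mttp (-0.42), needed for lipoprotein assembly, Baat (-0.50), which conjugates bile acids, and Ces1g (-1.19), a lipid hydrolase, were among those lower. Adh1 (-0.57), Hsd17b2 (-0.57), Acsl4 (-0.65), Sucnr1 (-0.91), Lect2 (-0.51) and Selenbp2 (-1.0) were lower too, while Serpina7, which encodes thyroxine-binding globulin (1.54, adjusted p = 0.0142), Acsm2 (1.17) and the lipoprotein receptor Vldlr (0.83) were higher. The groups did not overlap for 15 genes among all tested, where chance gives 1.10.

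All 24 genes of cholesterol synthesis and uptake were negative in this comparison, 14 of them lower when adjusted over the list alone and 2 over all genes, Ebp (-0.32) among them. Of 16 lipogenic genes 15 were negative and 10 lower when adjusted over the list alone, and of 28 lipoprotein genes 23 were negative and 3 lower, Mttp, Apoa1 (-0.55) and Tm6sf2 (-0.39). Of the 14 Kupffer and macrophage markers 13 were positive and 6 higher when adjusted over the list alone. With vehicle alone all 14 were positive (median 0.56), and with GW3965 alone 7 of 14 (median 0.04, camera adjusted p = 0.762; -0.15 with 3 of 14 positive without the libraries with a high mitochondrial share), so this count rests on the vehicle libraries. Over both treatments, with an estimated correlation, camera gave these 4 lists an adjusted p = 0.0803 each, and called 0 of 27 lists (5 at an unadjusted p below 0.05). Without the 5 libraries with a high mitochondrial share the adjusted p was 0.125 for cholesterol synthesis, 0.13 for lipogenesis and 0.404 for lipoproteins and for Kupffer cells, and 37 genes were called, 17 of them among the 30. Leaving out single libraries gave 9 (without replicate 3 of control vehicle) to 57 genes (without replicate 17 of Gata4LKO GW3965).

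Other splits of the libraries into groups of the same sizes were refitted. For genotype with vehicle, 1 of 35 splits, the real one, gave the 2 genes called, and the highest other split gave 1; for the lists 1 of 35 gave the 1 list, and the highest other gave 0. The real split thus stood alone for both, the smallest share that 35 splits allow. This argues against chance but does not exclude it, as both counts were small. For genotype with GW3965, 4 of 100 splits, the real one included, gave the 8 genes or more. This argues against chance but does not exclude it, since the highest other gave 2644. That split set replicates 9 and 12 of control and 14, 15 and 16 of Gata4LKO against the 4 libraries with a high mitochondrial share, and the next gave 477. This points to a structure of the samples that is larger than the genotype difference. For GW3965 in control, 1 of 35 splits gave the 106 genes and the highest other gave 9, which argues against chance. For its 2 lists, 3 of 35 splits gave as many and the highest other gave 2, so chance cannot be excluded for this count. The splits counted any list, so they do not test LXR targets and lipogenesis themselves. In control the LXR target score did not overlap, at 10.4 to 10.5 with vehicle and 11.2 to 11.8 with GW3965. For GW3965 in Gata4LKO, 2 of 100 splits gave the 33 genes or more, which argues against chance. The highest other, with 36, moved only replicate 15 of Gata4LKO GW3965 to the vehicle libraries. For the interaction, 1 of 100 splits gave the 2 genes, and the highest other gave 1. These splits exchanged treatment within genotype, which removes the response to GW3965 itself, so they leave open whether chance gave the 2 genes.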
